A study of Homo sapiens with 6 samples.

How the data were processed

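Per the labels, tumours were dissociated mechanically and with enzymes, red cells were lysed, some samples were tagged with hashtag antibodies, and droplet libraries of 5′ transcript ends were sequenced. The submitters' processing notes name Cell Ranger 7.0 with the GRCh38 build, and bcl2fastq and Seurat with no version; the release of the gene annotation is not stated. The deposited matrix held UMI counts, unnormalised, for 31551 genes and 74665 cells. The counts were checked to be whole numbers, and the UMI totals and numbers of detected genes recomputed from them equalled the deposited ones in all 74665 cells. The mitochondrial share was deposited as percent of each cell's UMIs, and its highest value was 20.0. The other columns, which the authors deposited as labels, hold a SingleR cell type, a copyKat copy number call, 1 of 29 clusters, a hashtag call and a level per library. Fewest detected genes per cell was 501, and the authors' cell filters are not stated. A stricter filter, at least 500 genes and under 10 percent mitochondrial UMIs, leaves 69571 cells.

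The authors' 20 cell type names were grouped into classes, among them hepatocyte-like cells (hepatocyte calls), T cells, macrophages and monocytes, and endothelial cells. A name was missing for 171 cells, and 386 cells were in no class. CD8 T cells were to be compared with CD4 T cells, and this was not run because the annotation does not separate them. The CD8 share of a tumour was instead taken, after the files were seen, as the percent of CD8A, CD8B and CD4 UMIs in its T cells that fell on CD8A and CD8B. No doublet caller was used. Shares of cells have exact Clopper-Pearson intervals at 95 percent, and SREBF1 levels of single tumours have exact Poisson intervals. Gene names were looked up in GENCODE 44 on GRCh38, which held 21354 of them (67.7 percent) and all 255 genes of the function lists; coordinates come from it, and the authors' release may differ. XIST, TSIX and Y-linked genes, 30 in all, were left out before testing.

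Counts were summed per tumour and class where a class had at least 20 cells, which gave 53 sums. They were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, quasi-likelihood fits with tumour as a block, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. All classes shared 1 estimate of the spread, from 53 sums with 38 residual degrees of freedom. SE and p therefore do not measure how a fold varies over the 6 tumours alone. Log2 fold changes are given with SE, and CPM values with TMM factors as mean ± SD over tumours. Levels in single tumours that are related to shares of cells are raw CPM on a log2 scale with 1 added.

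The 20 function lists are SREBP machinery, SREBP1 lipogenic, SREBP2 cholesterol, fatty acid oxidation, lipid uptake and storage, glycolysis, MHC class I and class II presentation, T cell attracting chemokines, interferon response, and ligands of inhibitory receptors. They further comprise T cell dysfunction, cytotoxicity, naive and central memory T, lipid associated macrophage, Wnt beta catenin targets in liver, TGF beta and matrix exclusion, hepatic secretory, proliferation, and dissociation stress. Another 13 lists hold cell type markers. The comparisons, lists, tests, alternatives and the rule for naming genes were chosen before the data were examined, except where the text says otherwise. Lists were tested with camera, at a correlation of 0.01 and at an estimated one, and with fry, on limma 3.58.1 voom values, with adjustment over the 20 lists of each comparison. Low counts removed 1 gene from the Wnt list and 1 from the secretory list. Named genes are the 7 of the SREBP machinery, the 3 with the smallest p among members past the threshold of each of 8 lists, and the 5 largest folds in each direction. The largest folds were taken outside the marker, immunoglobulin and T cell receptor genes, with a mean of at least 50 CPM over the sums compared. All but the machinery genes had to have the same direction in every tumour. The text prints part of these genes. Other members were named after their values were seen, where a count was small.

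Relations across tumours used Pearson's r and Spearman's rho with exact permutation over all 720 pairings (scipy 1.17.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3), adjusted over the 12 relations of each kind. Relations within tumours used hepatocyte-like cells thinned to 2000 UMIs each. Spearman's rho between the shares of UMIs in the SREBP1 list and in another list was taken in each tumour, the mean rho of 200 random lists matched on expression was subtracted, and the 6 excesses were tested by exact two-sided sign flips, adjusted over 4 relations. Free RNA was measured as the level of a class's marker genes in another class, in percent of their level in their own class.

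The gene test was checked on simulated counts with the totals and trended dispersions of the real sums. Each gene had 1 mean, shared by all classes and tumours, and no tumour effect. Folds were planted in 200 genes, as many up as down, and 18733 genes were tested. Planted 4-fold changes were recovered in 97.0, 93.9 and 92.4 percent of genes for T cells, macrophages and monocytes, and endothelial cells, and 2-fold changes in 31.3, 23.9 and 28.4 percent. False calls made up 4.21, 4.82 and 4.60 percent of the calls. In the real comparisons far more genes were called, with more higher than lower, so the simulation does not show errors of scaling or their rate of false calls. Alternatives changed 1 choice at a time, except that the DESeq2 1.42.0 test came with its own scaling. They were DESeq2 size factors in edgeR, that DESeq2 test, no count filter, sums of at least 50 cells, no tumour block, 2 classes in the fit, the stricter cell filter, cells with markers of another class left out, sums thinned to equal totals, and each tumour left out.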

Results

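Gene expression was measured in single cells of 6 primary hepatocellular carcinomas, with 1 droplet library of 5′ transcript ends per tumour. The labels place all 6 tumours in 1 group, so no groups of tumours were compared, and cell classes were compared within tumours instead. According to its title, the study concerns SREBP1, a regulator of lipid synthesis encoded by SREBF1, in tumour cells and the exclusion of immune cells. The matrix held 74665 cells, 31551 genes and 803000688 unique molecular identifiers (UMIs), each counting 1 captured transcript. Tumour 1 gave 64861190 UMIs in 8117 cells, tumour 2 gave 137309337 in 10713, and tumour 3 gave 201909613 in 19157. Tumour 4 gave 46869791 UMIs in 4830 cells, tumour 5 gave 147479504 in 10600, and tumour 6 gave 204571253 in 21248. The median cell held 5928 UMIs and 2237 detected genes, and the medians per tumour ran from 4828 UMIs in tumour 1 to 8668 in tumour 5. A deposited level per library called tumour 4 hot, tumours 1, 2 and 6 med, and tumours 3 and 5 cold. How that level was set is not stated, so it was described and not tested.

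T cells, macrophages and hepatocyte-like cells made up most of the cells, in shares that differed widely between tumours. T cells were 23.3% of the cells at the median of the 6 tumours. Their share ran from 4.82% in tumour 3 (95% exact Clopper-Pearson interval 4.52 to 5.14%) to 61% in tumour 4 (59.6 to 62.4%). It was 38.6%, 20% and 26.6% in tumours 1, 2 and 6, and 7.46% in tumour 5. Hepatocyte-like cells, which are the cells the authors' annotation calls hepatocytes, had a median share of 10.2%, from 2.48% in tumour 6 (2.27 to 2.69%) to 69.5% in tumour 5 (68.7 to 70.4%). Macrophages and monocytes had a median share of 25.8% (range 9.03 to 39.4%), and natural killer (NK) cells one of 10.3% (3.75 to 18.1%). Median shares were 3.94% for endothelial cells (1.58 to 22.9%), 1.09% for dendritic cells (0.509 to 6.34%) and 0.761% for B and plasma cells (0.308 to 8.31%). They were 0.720% for mesenchymal cells (0.165 to 4.69%) and 0.298% for neutrophils (0.0283 to 4.78%). Of 1600 epithelial calls, 1570 lay in tumour 2, while tumour 1 had 0 of 8117 cells, which allows a share of up to 0.0370%. The intervals and this limit, set at 3 counts, cover counting error only.

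**Figure D1:**
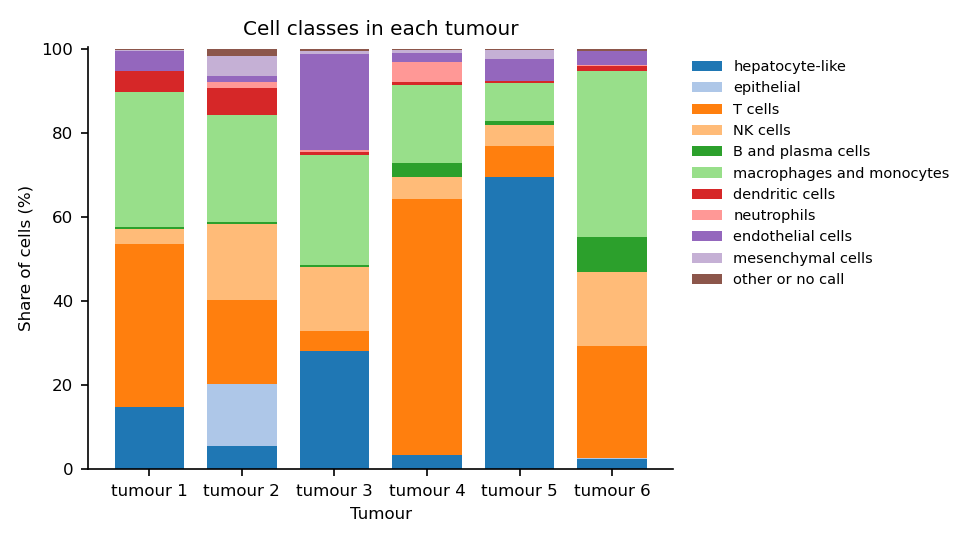
Each bar is 1 tumour and its segments are the percent of all cells in each cell class. T cells made up 61% of the cells in tumour 4 and 4.82% in tumour 3, and hepatocyte-like cells 69.5% in tumour 5 and 2.48% in tumour 6.

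Copy number calls by copyKat, deposited with the cells, named 72.0% of the called hepatocyte-like cells aneuploid, 9311 cells in all. They named 66.6% of the called epithelial cells aneuploid, 0.637% of T cells and 0.348% of endothelial cells. Among macrophages and monocytes the share was 33%, and 6114 of the 6184 aneuploid calls lay in tumour 6. In that tumour 7 of 474 called hepatocyte-like cells were aneuploid, or 1.48%, against 63.8 to 91.8% in the other tumours. The hepatocyte-like class therefore holds aneuploid and diploid calls, and the comparisons used all of its 15243 cells.

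Most genes of the SREBP machinery were higher in hepatocyte-like cells than in T cells of the same tumours. The comparison sets hepatocyte-like cells beside a class of the immune cells whose exclusion the title names. No liver without tumour was sampled. Neither it nor the later class comparisons can therefore separate a programme of tumour cells from one of hepatocytes in general. SREBF1 (chromosome 17, 17810399 to 17837002, GRCh38) encodes the SREBP1 factor of fatty acid synthesis. SREBF1 was 1.37 ± 0.33 log2 units higher (SE, adjusted p = 0.000344, both from the fit over all 53 sums). With these 2 classes alone in the fit it was not past the threshold (1.07, adjusted p = 0.0877). It stood at 36.4 ± 32.6 CPM (normalised counts scaled to an equal library total) against 11.7 ± 2.83 (SD, n = 6) and was higher in 4 of 6 tumours. SREBF2 (chromosome 22, 41833105 to 41907306), which encodes the SREBP2 factor of cholesterol synthesis, was 0.63 ± 0.23 higher (adjusted p = 0.0164, 5 of 6 tumours). INSIG1, whose product holds SREBPs in the endoplasmic reticulum, was 2.42 ± 0.45 higher, at 626 ± 534 against 99.4 ± 22.4 CPM (adjusted p = 9.95e-06, 5 of 6 tumours). INSIG2 (0.89 ± 0.25), the escort gene SCAP (0.74 ± 0.24) and the protease gene MBTPS2 (1.57 ± 0.26) were also higher, and the protease gene MBTPS1 was not past the threshold (−0.20 ± 0.19, adjusted p = 0.367). The machinery list thus had 6 of 7 genes higher and 0 lower, as many when adjusted over the list alone, and its median was 0.89. Its camera test, which compares a list with all other genes, was not past the threshold (adjusted p = 0.0958, and adjusted p = 0.381 with an estimated correlation), but was without tumour 2 (0.0496, range over alternatives 0.0279 to 0.606). With cells bearing markers of another class left out, a rule that deeper cells meet more easily, the list's median turned to −0.15. SREBF1 (−0.15, adjusted p = 0.864), SREBF2 (−0.56, 0.287) and SCAP (−0.57, 0.395) changed sign, with none past the threshold. In that setting INSIG1 (0.60, adjusted p = 0.502), INSIG2 (1.09, 0.0577) and MBTPS2 (1.52, 0.0590) were not past the threshold, each at the highest adjusted p of its alternatives.

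**Figure D2:**
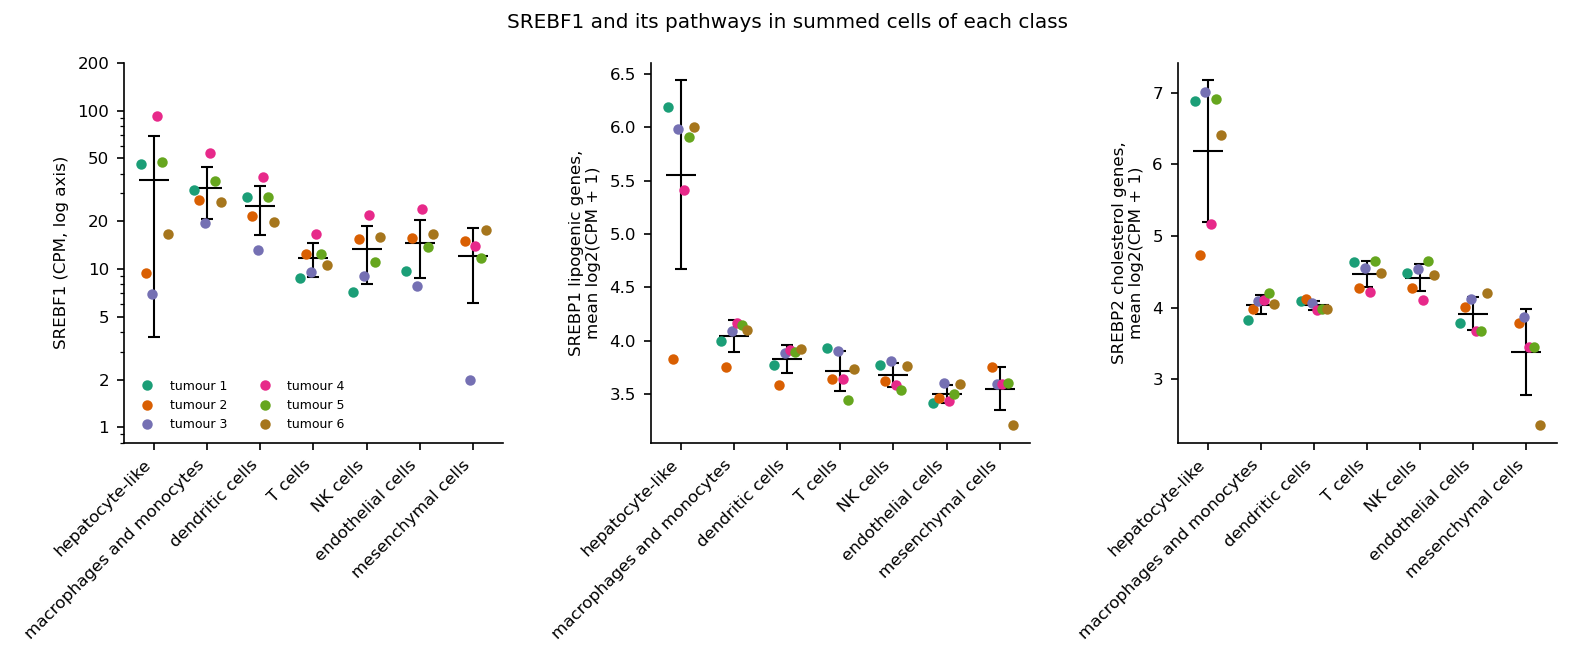
Levels by cell class of SREBF1 (CPM, log axis) and of the SREBP1 lipogenic and SREBP2 cholesterol lists (mean log2(CPM + 1) of the members); points are tumours and bars are the mean ± SD over 6 tumours, or 5 for mesenchymal cells. SREBF1 averaged 36.4 CPM in hepatocyte-like cells, 32.5 in macrophages and monocytes and 11.7 in T cells.

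Targets of both SREBP factors were higher in hepatocyte-like cells than in T cells, as were genes of fatty acid oxidation. Of 18 lipogenic SREBP1 target genes 16 were higher, 1 was lower (LPIN1, −1.37) and 1 was not past the threshold (ELOVL5, −0.49); adjusted over the list alone 16 were higher and 2 lower. FASN, the fatty acid synthase gene (chromosome 17, 82078338 to 82098294), was 3.01 ± 0.27 higher (112 ± 47.5 against 13.6 ± 1.86 CPM). The lipogenesis regulator THRSP was 5.02 ± 0.45 higher, and GPAM, which starts glycerolipid synthesis, 3.56 ± 0.36, each in 6 of 6 tumours. Of 24 cholesterol synthesis genes regulated by SREBP2, 20 were higher and 0 lower, as many adjusted over the list alone, and STARD4, IDI1, SC5D and MVD were not past the threshold. The sterol reductase gene TM7SF2 (4.20 ± 0.39) and the sterol-regulated TMEM97 (4.25 ± 0.41) were higher in 6 of 6 tumours. Of 16 fatty acid oxidation genes 14 were higher and 0 lower, as many over the list alone, among them ECHS1 (2.74 ± 0.25) and EHHADH (4.13 ± 0.39). CPT1A (0.00) and SLC25A20 (−0.07) were not past the threshold. The list medians were 2.17 for SREBP1 (camera adjusted p = 9.30e-05), 1.93 for SREBP2 (7.01e-06) and 1.58 for oxidation (7.01e-06). With an estimated correlation none of these held (adjusted p = 0.189, 0.270 and 0.0994). With marker-bearing cells left out the medians were 1.29, 0.93 and 1.15 and the calls were lost (0.193, 0.225 and 0.0683, each the highest of a range that starts at 6.09e-07, 3.92e-09 and 7.03e-09), with 10 SREBP1 targets higher and 2 lower, and as many SREBP2 targets. Lipid uptake and storage genes were split, with 6 higher, 3 lower and 6 not past the threshold (5 and 2 adjusted over the list alone; median 0.94, camera adjusted p = 0.488). The lipoprotein receptor SCARB1 (4.53 ± 0.40) and the triglyceride enzyme DGAT1 (1.44 ± 0.25, but −0.18 with marker-bearing cells left out) were higher, and the cholesterol exporter ABCG1 (−2.95 ± 0.30), SOAT1 and FABP5 were lower.

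Most MHC class I genes, and part of the class II and interferon response genes, were lower in hepatocyte-like cells than in T cells. Of 16 MHC class I presentation genes 12 were lower, the chaperones PDIA3 (0.84) and CALR (0.87) were higher, and PSMB8 and TAPBP were not past the threshold, with the same counts over the list alone. NLRC5, the transactivator of class I genes, was −2.85 ± 0.20 (9.57 ± 3.4 against 71.3 ± 27.2 CPM), HLA-F −2.15 ± 0.25 and HLA-E, a ligand of NKG2A, −1.75 ± 0.22, each lower in 6 of 6 tumours. The list median was −1.48 (camera adjusted p = 1.20e-05, and adjusted p = 0.194 with an estimated correlation). Of 10 MHC class II genes 6 were lower, 0 higher and 4 not past the threshold (HLA-DRA, HLA-DMA, HLA-DMB and CIITA), with a median of −1.02 and camera adjusted p = 0.0271 (0.0753 without tumour 2, range 9.79e-05 to 0.0753, and adjusted p = 0.484 with an estimated correlation). Of 19 interferon response genes 8 were lower, 2 higher (IFIT1, 1.47, and IFI27, 1.68) and 9 not past the threshold, with a median of −0.41. GBP5 (−4.39 ± 0.36) and GBP4 (−2.53 ± 0.37), interferon-induced GTPases, and the factor gene IRF1 (−1.95 ± 0.29) were lower in 6 of 6 tumours. That camera call was narrow (adjusted p = 0.0472, and adjusted p = 0.451 with an estimated correlation) and was lost in 7 alternatives. These were DESeq2 size factors (0.0560), no tumour block (0.0653), 2 classes in the fit (0.0752), the stricter cell filter (0.0627), epithelial calls added (0.0749), and tumour 2 (0.0753) or 4 (0.0778) left out, over a range of 0.000569 to 0.0778.

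Chemokine and inhibitory ligand genes went both ways against T cells. Of 12 chemokine genes that attract T cells 6 were higher (7 over the list alone), CCL5 (−4.65 ± 0.41) and CCL4 (−2.70 ± 0.56) were lower, and CXCL9, CXCL16, CCL19 and CCL3 were not past the threshold. The CXCR3 ligand CXCL11 was 3.37 ± 0.66 higher, at 4.12 ± 4.19 against 0.323 ± 0.387 CPM, and was not past the threshold with marker-bearing cells left out (2.23, adjusted p = 0.412, range 1.48e-06 to 0.412). The list median was 1.22 (camera adjusted p = 0.854). Of 12 ligands of inhibitory receptors FGL1, a LAG3 ligand (6.64 ± 0.56, 1788 ± 1411 against 31.5 ± 35.0 CPM), the TIGIT ligands PVR (4.34 ± 0.44) and NECTIN2 (4.16), and VTCN1 (4.63) were higher. Another 6 were lower, among them VSIR (−2.61 ± 0.29), while CD86 and PDCD1LG2 were not past the threshold, with equal counts over the list alone. The median of that list was −0.88, its mean was 0.59 and its camera adjusted p was 0.290.

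Among the remaining lists, 10 of 13 glycolysis genes were lower (median −1.80, camera adjusted p = 0.000473), with ENO1, GAPDH and ALDOA not past the threshold. With an estimated correlation only the dysfunction (adjusted p = 0.0277) and naive lists (0.0115) of this comparison held, and glycolysis (0.167), proliferation (0.358), secretory (0.0994), cytotoxicity (0.0994), Wnt (0.381) and TGF beta (0.138) did not. Proliferation genes had 8 of 11 lower (9 over the list alone; median −1.45, adjusted p = 0.00116), with CCNB1, BIRC5 and UBE2C not past the threshold. All 9 tested hepatic secretory genes were higher (median 6.47, adjusted p = 1.19e-07). Of 9 tested Wnt target genes 7 were higher and NKD1 and AXIN2 not past the threshold (median 2.84, adjusted p = 0.0312). That call was lost in 7 alternatives, with DESeq2 size factors (0.0560), no block (0.0810), 2 classes in the fit (0.0752), thinned sums (0.0950), epithelial calls added (0.0654), marker-bearing cells left out (0.219) and tumour 3 left out (0.162), over a range of 0.00128 to 0.219. Of 11 TGF beta and matrix genes 9 were higher, TGFB1 (−2.69) was lower and TGFBR2 was not past the threshold (median 3.04, adjusted p = 0.0303, and 0.0560 with DESeq2 size factors, range 0.00803 to 0.0560). The T cell lists were lower throughout, with 11 of 11 dysfunction (median −3.88, adjusted p = 4.36e-08), 11 of 11 cytotoxicity (−4.19, 1.46e-08) and 9 of 9 naive and central memory genes (−4.80, 1.91e-07). The classes had been called from the same expression values. Lower T cell genes here, and higher secretory genes in each of the 3 comparisons, were therefore given beforehand, and nothing further is read from their p values. The lipid associated macrophage list had SPP1, CD9, APOE and APOC1 higher, FABP5 lower and 5 genes not past the threshold (median 0.88, adjusted p = 0.182). FABP5 and LPL belong to both that list and the lipid uptake list. Dissociation stress genes had 4 higher (EGR1, ATF3, FOS and FOSB), JUNB lower and 7 not past the threshold (median 0.69, adjusted p = 0.290).

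Across all 20210 genes tested against T cells, 7606 were higher, 4866 lower and 7738 not past the threshold, with a median log2 fold change of 0.31. The largest folds among abundant genes were those of the bile salt exporter ABCB11 (7.12 ± 0.60), the acute phase genes SAA1 (7.07 ± 0.97), CRP (7.0 ± 0.82) and LBP (7.06 ± 0.47), and the plasma protein gene HRG (6.95 ± 0.43). Without tumour 6 the folds of SAA1, CRP, FGL1 and THRSP were 6.23, 6.25, 6.01 and 4.4, and without tumour 3 that of ABCB11 was 7.86. The largest falls were those of T cell genes, namely the checkpoint receptor CTLA4 (−6.04 ± 0.52), CD5 (−5.94 ± 0.37), the costimulator ICOS (−5.93 ± 0.46), GPR171 (−5.79 ± 0.43) and the interleukin receptor IL7R (−5.51 ± 0.46). Hepatocyte marker genes in T cells stood at a median of 2.60% of their level in hepatocyte-like cells (range 0.388 to 6.58%), and T cell markers in hepatocyte-like cells at 1.55% (0.660 to 3.54%). SREBF1 was not past the threshold when the fit held these 2 classes alone (1.07, adjusted p = 0.0877), and its sign reversed once cells with markers of another class were left out (−0.15, adjusted p = 0.864; range over alternatives 3.80e-05 to 0.864). SREBF2 was not past it without tumour 1 (0.58, adjusted p = 0.0503) or tumour 5 (0.40, adjusted p = 0.168), over a range of 0.00266 to 0.168 with 1 tumour left out.

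**Figure D3:**
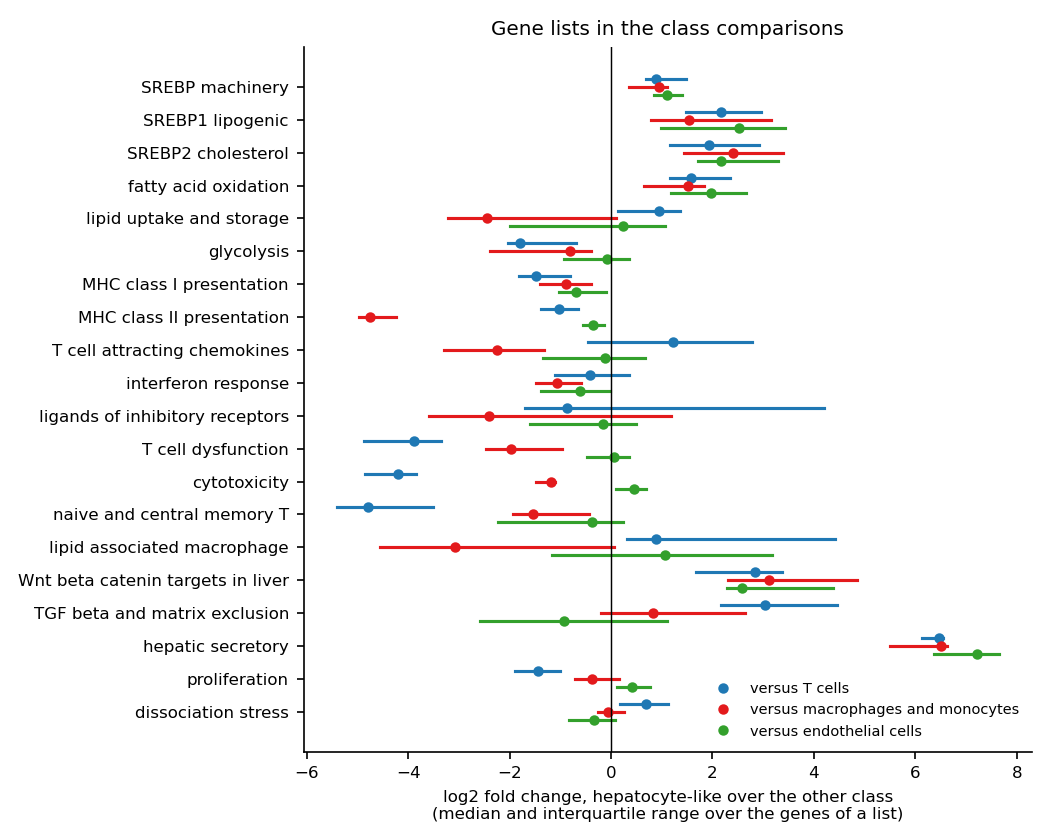
Log2 fold changes of hepatocyte-like cells against T cells, macrophages and monocytes, and endothelial cells for 20 gene lists; points are the median of a list's members and bars the interquartile range. The hepatic secretory list was highest, at 6.47, 6.51 and 7.21, a direction given beforehand by classes called from the same expression values.

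Against macrophages and monocytes no difference in SREBF1 was past the threshold, while the targets of both SREBP factors were higher in hepatocyte-like cells. This comparison asks which part of the lipid programme sets the hepatocyte-like cells apart from the main myeloid class. SREBF1 stood at 36.4 ± 32.6 CPM in hepatocyte-like cells and 32.5 ± 11.9 in macrophages and monocytes (SD, n = 6), a log2 fold change of −0.05 ± 0.31 (SE, adjusted p = 0.898, 3 of 6 tumours higher) whose sign turned with DESeq2 size factors (0.12). SREBF2 was 1.17 ± 0.23 higher (adjusted p = 3.28e-05, 5 of 6 tumours), and SCAP (1.07 ± 0.24), INSIG2 (1.13 ± 0.25) and MBTPS2 (0.95 ± 0.25) were higher in 6 of 6. INSIG1 (0.52 ± 0.43, adjusted p = 0.304) and MBTPS1 (0.20 ± 0.18, adjusted p = 0.353) were not past the threshold, although INSIG1 was without tumour 4 (1.09, adjusted p = 0.0468, range 0.0468 to 0.825), and MBTPS1 was in the DESeq2 test with its own scaling (0.36, adjusted p = 0.00219, range 0.00219 to 0.828). The machinery list had 4 of 7 higher and 0 lower, as many over the list alone (median 0.95, camera adjusted p = 0.102, adjusted p = 0.331 with an estimated correlation, and 0.0477 without tumour 2, range 0.0342 to 0.669). With marker-bearing cells left out SREBF2 (0.21, adjusted p = 0.744), SCAP (0.58, 0.410) and MBTPS2 (1.40, 0.0901) were not past the threshold, each at the highest adjusted p of its alternatives, and INSIG1 turned to −1.38.

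Of the 18 SREBP1 targets 15 were higher (16 over the list alone) and ME1, a source of NADPH, was lower (−1.06), a call that was lost with DESeq2 size factors, while LPIN1 and ACSS2 were not past the threshold. With marker-bearing cells left out 7 were higher. FASN was 3.51 ± 0.28 higher (112 ± 47.5 against 9.72 ± 2.67 CPM), THRSP 5.91 ± 0.45 and the elongase gene ELOVL6 4.34 ± 0.40, each in 6 of 6 tumours. Of the 24 SREBP2 targets 22 were higher and 0 lower, as many over the list alone, with STARD4 and LSS not past the threshold. TM7SF2 was 4.73 ± 0.40 higher and FDPS of isoprenoid synthesis 2.89 ± 0.27. Of the 16 oxidation genes 15 were higher and HADHA was not past the threshold, with EHHADH at 3.76 ± 0.38 and ECHS1 at 2.08 ± 0.24. The list medians were 1.54 for SREBP1 (camera adjusted p = 0.000173), 2.41 for SREBP2 (6.25e-09) and 1.51 for oxidation (1.23e-05), and none held with an estimated correlation (adjusted p = 0.146, 0.146 and 0.137). Uptake and storage ran the other way, with 11 of 15 genes lower and DGAT1, DGAT2, VLDLR and SCARB1 higher (median −2.44, adjusted p = 0.00145, and adjusted p = 0.146 with an estimated correlation). The scavenger receptor MSR1 was −4.98 ± 0.49, the lysosomal lipase LIPA −3.25 ± 0.36 and ABCG1 −3.18 ± 0.30, each lower in 6 of 6 tumours.

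All MHC class II genes, and part of the class I, chemokine and interferon genes, were lower in hepatocyte-like cells than in macrophages and monocytes. The 10 class II genes had a median of −4.75 (camera adjusted p = 3.63e-09, and adjusted p = 0.137 with an estimated correlation). Of 16 class I genes 12 were lower, PDIA3 (0.92) was higher, and PSMB8, TAPBP and CALR were not past the threshold (2 higher and 12 lower over the list alone; median −0.89, adjusted p = 0.00155, and adjusted p = 0.277 with an estimated correlation). NLRC5 was −1.72 ± 0.19, the immunoproteasome gene PSMB10 −1.65 ± 0.22 and HLA-E −1.64 ± 0.22. Of 12 chemokine genes 7 were lower and 0 higher (median −2.25, adjusted p = 0.00216, and adjusted p = 0.137 with an estimated correlation), with CCL20, CXCL10, CCL19, CCL21 and CCL2 not past the threshold. The CXCR3 ligand CXCL9 was −4.18 ± 0.50 (18.5 ± 29.4 against 419 ± 811 CPM), CCL3 −4.66 ± 0.62 and CCL4 −4.19 ± 0.60. Of 19 interferon genes 13 were lower and 0 higher (median −1.06, adjusted p = 0.000213, and adjusted p = 0.146 with an estimated correlation), among them GBP5 (−3.39 ± 0.35), GBP4 (−2.49 ± 0.37) and IFI44L (−2.59 ± 0.41). Among inhibitory ligands FGL1 (6.79 ± 0.56), PVR (1.93) and VTCN1 (4.43) were higher, 8 were lower and NECTIN2 was not past the threshold (4 and 8 over the list alone; median −2.40, adjusted p = 0.0163, adjusted p = 0.193 with an estimated correlation, and 0.0851 with 2 classes in the fit, range 0.00447 to 0.0851). The costimulatory ligand CD86 was −5.28 ± 0.48 and VSIR −3.54 ± 0.30.

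Of the other lists, hepatic secretory genes were higher in 9 of 9 (median 6.51, camera adjusted p = 5.69e-08) and Wnt targets in 7 of 9, with GLUL lower (−1.13) and NKD1 not past the threshold (median 3.11, adjusted p = 0.0121; 0.131 without tumour 3, range 0.000250 to 0.466). None of the 20 lists held against macrophages with an estimated correlation, where the lowest adjusted p was 0.137 and the Wnt list had 0.269. The lipid associated macrophage list had 7 of 10 lower and APOC1 higher, with SPP1 and APOE not past the threshold (median −3.08, adjusted p = 0.00202). Glycolysis had 7 of 13 lower (median −0.80, adjusted p = 0.00151). Dysfunction had 8 of 11 lower (median −1.98, adjusted p = 0.00151), cytotoxicity 8 of 11 (9 over the list alone; −1.19, 0.0157, and −0.44, 0.611 with marker-bearing cells left out, range 0.00257 to 0.611), and naive and central memory genes 6 of 9 (−1.54, 0.0299; 0.0513 without tumour 2, range 0.0109 to 0.370). T cell markers stood at a median of 5.26% of their own level in macrophages and monocytes (1.67 to 11.3%). In hepatocyte-like cells they stood at 1.55%. T cell RNA in the macrophage sums could thus contribute to the calls of these 3 T cell lists, which was not tested. TGF beta and matrix genes were split, with 5 genes higher, among them FN1 and COL4A1, and TGFBI and TGFB1 lower (median 0.83, adjusted p = 0.369). Proliferation had MKI67 and MCM5 lower (median −0.38, adjusted p = 0.311). Dissociation stress had JUN higher and JUNB, FOSB and DUSP1 lower (1 and 2 over the list alone; median −0.07, adjusted p = 0.614), and the sign of that median turned with DESeq2 size factors.

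Of 20210 genes, 6718 were higher than in macrophages and monocytes, 5354 lower and 8138 not past the threshold, with a median log2 fold change of 0.16. The largest folds were those of the plasma protein genes AHSG (7.19 ± 0.48), HRG (7.12 ± 0.43), LBP (7.10 ± 0.46) and SAA4 (7.05 ± 0.52) and the cytochrome gene CYP2A6 (7.05 ± 0.55). The largest falls were those of HLA-DQA2 (−5.71 ± 0.59), which had 0 counts in at least 1 hepatocyte-like sum, the chemokine CCL18 (−5.53 ± 0.66, and −6.38 without tumour 3), HS3ST2 (−5.48 ± 0.61), SLC16A10 (−5.44 ± 0.51) and the formyl peptide receptor FPR3 (−5.43 ± 0.50). Hepatocyte markers in macrophages and monocytes stood at 2.76% of their own level (0.532 to 5.05%), and macrophage markers in hepatocyte-like cells at 2.06% (0.354 to 7.71%). With cells bearing markers of another class left out, SREBF1 was lower in hepatocyte-like cells (−1.36, adjusted p = 0.0470, range over alternatives 0.0470 to 0.946), and the SREBP1 list was not past the threshold (camera adjusted p = 0.370, range 1.63e-06 to 0.370).

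Against endothelial cells, the vessel lining that immune cells cross, most SREBP machinery genes and most targets of both factors were higher in hepatocyte-like cells. SREBF1 was 1.11 ± 0.32 log2 units higher (36.4 ± 32.6 against 14.6 ± 5.76 CPM, SD, n = 6, adjusted p = 0.00367, 4 of 6 tumours). SREBF2 was 1.19 ± 0.24 higher, SCAP 1.04 ± 0.25, INSIG1 2.67 ± 0.46, INSIG2 1.60 ± 0.26 and MBTPS2 0.67 ± 0.26 (adjusted p = 0.0270), while MBTPS1 was lower (−0.44 ± 0.19, adjusted p = 0.0444, 6 of 6 tumours). MBTPS1 was not past the threshold without tumour 1 (adjusted p = 0.137), 2 (0.0776), 3 (0.0722) or 4 (0.323), and MBTPS2 was not without tumour 3 (0.0863), 5 (0.0501) or 6 (0.103), over ranges of 4.72e-05 to 0.419 and 0.00306 to 0.457. The machinery list had 6 higher and 1 lower, as many over the list alone (median 1.11, camera adjusted p = 0.0667, adjusted p = 0.430 with an estimated correlation, and 0.0287 without tumour 2, range 0.00960 to 0.797). With marker-bearing cells left out its median turned to −0.16, and SREBF1 (−0.55, adjusted p = 0.601), SREBF2 (−0.36, 0.645), SCAP (−0.16) and INSIG1 (−0.026) reversed. Of 18 SREBP1 targets 14 were higher (15 over the list alone) and 0 lower, with LPIN1, ELOVL5, ACACB and ACLY not past the threshold. FASN was 3.34 ± 0.28 higher (112 ± 47.5 against 10.6 ± 1.21 CPM), the desaturase gene SCD 5.14 ± 0.46 (233 ± 121 against 6.53 ± 2.74 CPM) and THRSP 6.63 ± 0.52. Of 24 SREBP2 targets 23 were higher and STARD4 was not past the threshold, with TM7SF2 at 5.56 ± 0.43, TMEM97 at 4.79 ± 0.44 and EBP of sterol synthesis at 3.47 ± 0.31. Of 16 oxidation genes 15 were higher and CPT1A was not past the threshold, with EHHADH at 3.69 ± 0.39 and ECHS1 at 2.66 ± 0.25. The medians were 2.53 for SREBP1 (camera adjusted p = 1.57e-06), 2.18 for SREBP2 (7.83e-11) and 1.96 for oxidation (1.28e-08), and none held with an estimated correlation (adjusted p = 0.157, 0.157 and 0.0719). With marker-bearing cells left out 9 SREBP1 targets were higher and 1 lower, as were 9 and 1 SREBP2 targets, and the SREBP1 call was lost (median 1.40, adjusted p = 0.116, range 3.68e-10 to 0.116). Uptake and storage genes were split with 5 higher, 5 lower and 5 not past the threshold (median 0.23, mean −0.27, adjusted p = 0.537), and were lower as a list with marker-bearing cells left out (median −0.97, adjusted p = 0.00531, range 0.00531 to 0.879, and adjusted p = 0.173 with an estimated correlation). The triglyceride enzyme DGAT2, not past the threshold with marker-bearing cells left out (6.93, adjusted p = 0.0625, range 3.09e-18 to 0.0625), was 5.83 ± 0.64 higher, and the fatty acid receptor CD36 (−3.84 ± 0.58) and ABCG1 (−3.43 ± 0.31) were lower.

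Against endothelial cells, immune genes went both ways. Of 16 MHC class I genes 8 were lower, TAPBP, PDIA3 and CALR were higher and 5 were not past the threshold (median −0.69), with NLRC5 at −1.67 ± 0.20, HLA-E at −1.90 ± 0.23 and HLA-F at −1.26 ± 0.25. That list's camera call (adjusted p = 0.0401, and adjusted p = 0.688 with an estimated correlation) was lost in 6 alternatives. These were no tumour block (0.129), 2 classes in the fit (0.0693), the stricter cell filter (0.0555), epithelial calls added (0.0576), and tumour 3 (0.136) or 4 (0.0840) left out, over a range of 8.56e-05 to 0.136. Of 10 class II genes HLA-DRB1 (−1.12) was lower, and none was over the list alone (median −0.36, adjusted p = 0.308). With marker-bearing cells left out that list was lower (median −2.75, adjusted p = 8.56e-05, range 8.56e-05 to 0.540, and adjusted p = 0.213 with an estimated correlation). Of 12 chemokine genes the CCR6 ligand CCL20 was higher (5.63 ± 0.86, 188 ± 166 against 3.01 ± 3.33 CPM) and CXCL12 (−4.31 ± 0.61), CCL21 (−5.08 ± 0.88) and CXCL11 (−1.22) were lower, 1 and 2 over the list alone (median −0.12, adjusted p = 0.587). Leaving out 1 tumour moved CCL20 between 4.93 without tumour 5 and 6.45 without tumour 6, CCL21 between −4.18 without tumour 2 and −6.08 without tumour 3, and CXCL12 to −3.71 without tumour 4. Of 19 interferon genes 8 were lower, GBP2 (0.91) was higher and 10 were not past the threshold, with a median of −0.62 and camera adjusted p = 0.05, among them IFI44L (−3.64 ± 0.42), IFI27 (−3.75 ± 0.59) and GBP4 (−3.12 ± 0.38). That list was past the threshold in 8 alternatives, among them those without tumour 1 (0.0193), 2 (0.0198) or 5 (0.0499), over a range of 0.000133 to 0.223, and in none of the 8 with an estimated correlation (adjusted p = 0.481, 0.513 and 0.598 without those tumours, and 0.246 at the lowest). FGL1 (7.66 ± 0.59) and VTCN1 (5.38) were the inhibitory ligands that were higher, and LGALS9 (−2.34 ± 0.35), VSIR (−1.93 ± 0.29), PDCD1LG2, CD274 and TNFRSF14 were lower (median −0.16, mean 0.48, adjusted p = 0.537).

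Of the other lists against endothelial cells, secretory genes were higher in 9 of 9 (median 7.21, camera adjusted p = 9.89e-10) and Wnt targets in 8 of 9, with AXIN2 not past the threshold (2.58, 0.00117; 0.291 with marker-bearing cells left out, range 2.71e-06 to 0.291). None of the 20 lists held with an estimated correlation, where the secretory list had adjusted p = 0.0719, the lowest, and the Wnt list 0.308. TGF beta and matrix genes had COL4A1, COL4A2, TGFBR2, TGFB3 and TGFB1 lower and FN1, TGFBI and VEGFA higher (median −0.92, adjusted p = 0.125). Glycolysis had HK1, SLC2A3, PFKP and PKM lower and ENO1 and LDHA higher (−0.08, 0.296). The lipid associated macrophage list had 5 higher and LPL, FABP5 and CD9 lower (6 and 3 over the list alone; median 1.06, adjusted p = 0.445). Dysfunction had ENTPD1 and LAYN lower (median 0.06, mean −0.43, adjusted p = 0.308 in the lower direction), and cytotoxicity had KLRG1 lower (median 0.45, adjusted p = 0.983 in the lower direction). Naive and central memory genes had S1PR1, LEF1 and KLF2 lower (−0.37, 0.155). Proliferation had CCNB1 and BIRC5 higher (1 over the list alone; 0.42, 0.542), and dissociation stress had ATF3 higher and FOS, FOSB, JUNB and IER2 lower (−0.34, 0.280).

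Of 20210 genes, 5884 were higher than in endothelial cells, 4624 lower and 9702 not past the threshold, with a median log2 fold change of 0.14. The largest folds were those of SAA1 (8.26 ± 1.03), PRAP1 (8.05 ± 0.53), HRG (8.05 ± 0.46), LBP (8.02 ± 0.52) and CRP (7.94 ± 0.84). Without tumour 6 SAA1, PRAP1, CRP and FGL1 stood at 7.33, 7.42, 7.06 and 7.07. The largest falls were those of the vessel genes ACKR1 (−6.80 ± 0.78; −5.75 without tumour 2 and −7.79 without tumour 6), CLEC14A (−6.41 ± 0.66), SOX17 (−6.31 ± 0.57), PREX2 (−6.27 ± 0.60) and CD34 (−6.26 ± 0.63), each with 0 counts in at least 1 hepatocyte-like sum, as was CCL21. Hepatocyte markers in endothelial cells stood at 2.06% of their own level (0.414 to 2.88%), and endothelial markers in hepatocyte-like cells at 1.09% (0.171 to 5.91%). SREBF1 was not past the threshold with 2 classes in the fit (0.73, adjusted p = 0.208) and its sign reversed with marker-bearing cells left out (−0.55, adjusted p = 0.601, range over alternatives 0.00151 to 0.601). The fry test, which asks whether a list's genes move, on balance, one way and compares it with no other genes, gave the SREBP1 list adjusted p = 2.12e-12 against T cells and the SREBP2 list 2.09e-10. Scaling by DESeq2 size factors moved the median of all genes from 0.31 to 0.48 against T cells and from 0.16 to 0.31 against macrophages, and to 0.08 against endothelial cells, and all folds shift with it.

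SREBF1 in hepatocyte-like cells was highest in the tumour with the largest share of T cells, a comparison across tumours that bears on the title's question of immune exclusion. It stood at 95.6 CPM in tumour 4 (95% exact Poisson interval 87.2 to 105), where T cells made up 61% of cells, and at 4.97 CPM (4.55 to 5.41) in tumour 3, where they made up 4.82%. The value of tumour 4 rests on 481 SREBF1 UMIs in 159 hepatocyte-like cells. These Poisson intervals cover counting error only, and not variation between cells. The other tumours had 30.5 CPM (tumour 1), 25.4 (tumour 5), 12.1 (tumour 6) and 10.3 (tumour 2). These are raw CPM. With the TMM factors of the class comparisons, tumours 1 to 6 had 45.8, 9.43, 6.91, 92.3, 47.1 and 16.6 CPM. The relations below were not computed on that scale. Over the 6 tumours Pearson's r was 0.826 (exact permutation p = 0.0472, adjusted p = 0.567 over 12 relations) and Spearman's rho 0.829 (exact permutation p = 0.0583, adjusted p = 0.617), both two-sided. Without the pair of tumours farthest from the median of SREBF1 r was 0.154 over the 4 tumours left. That step also narrows the range of SREBF1, so it does not show which tumours carry the relation. Without tumour 4 r was 0.529 (exact p = 0.383, adjusted p = 0.875, range over leaving out 1 tumour 0.1 to 0.875). The SREBP1 list mean had no relation to the T cell share that held (r = 0.272, exact p = 0.571; rho = 0.314, exact p = 0.564; r = −0.241 without the farthest pair), with adjusted p = 0.944 and 0.846. Nor had the SREBP2 list mean (r = −0.415, exact p = 0.408; rho = −0.429, exact p = 0.419; r = −0.212 without the farthest pair), with adjusted p = 0.919 and 0.846.

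The other 9 relations set SREBF1, the SREBP1 list and the SREBP2 list against the CD8 share of T cells, MHC class I genes and T cell attracting chemokine genes. Their r lay between −0.504 and 0.550 (exact permutation p 0.257 to 0.958, adjusted p 0.919 to 0.958) and their rho between −0.771 and 0.600 (exact permutation p 0.103 to 1). The lowest rho was that of the SREBP2 list and the CD8 share, the part of CD8A, CD8B and CD4 UMIs in T cells that fell on CD8A and CD8B. That share was 64.6% in tumour 1, 75.0% in tumours 2 and 5, 71.6% in tumour 3, 87.9% in tumour 4 and 84.4% in tumour 6. Without the farthest pair of tumours these 9 had r between −0.915 and 0.597. Of the 12 relations 1 had an unadjusted Pearson p under 0.05 and 0 an unadjusted Spearman p, and 0 held after adjustment. The smallest p that 720 pairings can give is 0.00139. The libraries were sequenced at 1 or both of 2 sites. The library names of tumours 1, 2, 3 and 5 carry a mark of combination that those of tumours 4 and 6 lack, and its meaning is not stated. SREBF1 was 4.97 to 30.5 CPM in the 4 tumours with the mark and 95.6 and 12.1 CPM in the 2 without it. Further marks in the library names are Novogene in that of tumour 5 alone and GEX in those of tumours 3, 4 and 6. The relation was not computed within these small parts, so batch and tumour were not told apart. Hashtag calls exist in tumours 2, 3, 4 and 5, again fewer than the 6 over which relations were reported.

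**Figure D4:**
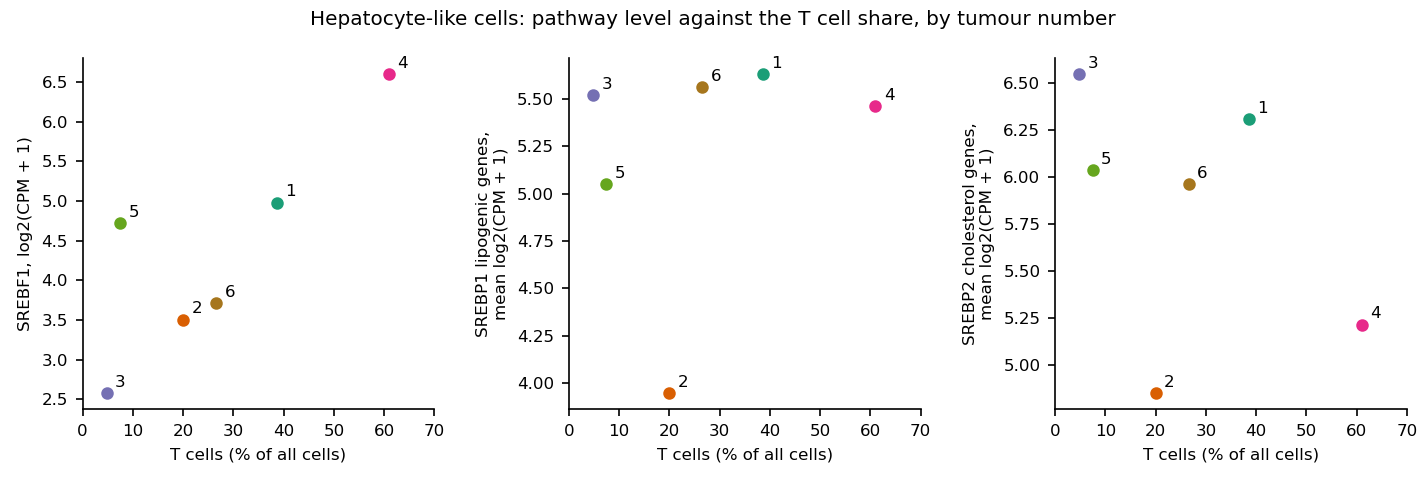
SREBF1, the SREBP1 list and the SREBP2 list in hepatocyte-like cells (y axes, log2(raw CPM + 1) and list means of it) against T cells as percent of all cells (x axes). Each point is 1 tumour. Pearson's r was 0.826, 0.272 and −0.415.

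On average over tumours, hepatocyte-like cells with a larger share of SREBP1 target UMIs had a larger share of SREBP2 target and fatty acid oxidation UMIs and a smaller share of interferon response UMIs. Single tumours did not all show it, as in tumour 2 the SREBP2 excess was 0.00196 and the interferon excess −0.00299, and in tumour 4 the oxidation excess was 0.0126. This comparison asks how the lipogenic programme goes with the others from cell to cell, in 134 to 6308 cells per tumour. The SREBP2 list's Spearman rho exceeded that of 200 matched random lists by 0.279 ± 0.168 (SD, n = 6 tumours, above 0 in 6 of 6; exact sign-flip permutation p = 0.03125, adjusted p = 0.0417), and it was highest in tumour 1 (0.437). Fatty acid oxidation exceeded it by 0.101 ± 0.0794 (6 of 6 above 0, exact permutation p = 0.03125, adjusted p = 0.0417). The excess for interferon response was −0.101 ± 0.0850 (0 of 6 above 0, exact permutation p = 0.03125, adjusted p = 0.0417). MHC class I presentation was not past the threshold (−0.0798 ± 0.137, 2 of 6 above 0, exact permutation p = 0.1875). These p values ask whether a list's excess keeps its sign over tumours, and do not measure the spread between random lists. Of the 200 random lists, 111 (tumour 2) to 200 (tumour 3) had a rho at or above that of interferon response. For oxidation 1 (tumour 6) to 86 (tumour 4) did, and for SREBP2 0 to 100, the latter in tumour 2. For 6 tumours 0.03125 is the smallest exact permutation p this two-sided test can give, so leaving out any tumour ends each call, at p = 0.0625. Over 10 draws of the thinning the means were 0.251, 0.115, −0.0880 and −0.0581, and the oxidation call was past the threshold in 8 single draws and the interferon call in 5. With cells shuffled within tumours the 4 means over 10 shuffles lay between −0.00342 and 0.00780, and single shuffles between −0.0281 and 0.0497.

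**Figure D5:**
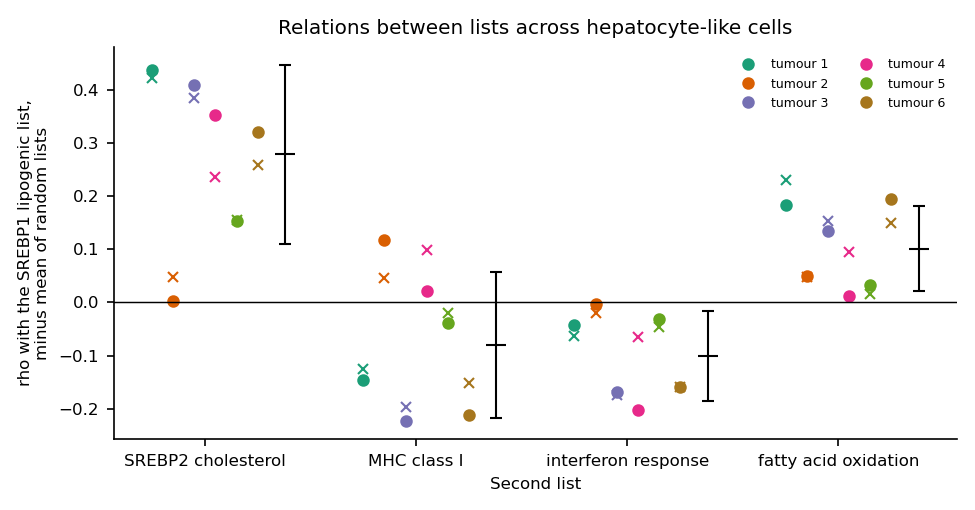
Excess of Spearman's rho over matched random lists (y axis) between the share of SREBP1 lipogenic UMIs and that of 4 other lists (x axis), across hepatocyte-like cells; dots are tumours in the reported draw, crosses the mean of 10 draws, and black marks the mean ± SD over 6 tumours. The means were 0.279 for SREBP2, 0.101 for fatty acid oxidation, −0.101 for interferon response and −0.0798 for MHC class I.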

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

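The tests of chance among the relations, of total RNA and mitochondrial share, and of cells of other classes were chosen only after the result was seen, as were the alternatives that used hepatocyte clusters only or the mean of 10 thinning draws.

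In 23 groups of 6 tumours, 6 held a tumour far from the others by Dixon's test at its 95 percent critical value, where chance gives about 1 in 20. SREBF1 in hepatocyte-like cells was 95.6 raw CPM in tumour 4 and at most 30.5 in the others. With TMM factors it was 92.3 CPM in tumour 4 and at most 47.1 in the others, a narrower gap on which Dixon's test was not run. The SREBP1 list mean was 3.95 in tumour 2 and at least 5.05 in the others. Epithelial calls were 14.7% of the cells of tumour 2 and at most 0.136% elsewhere. Endothelial cells were 22.9% of tumour 3 and at most 5.30% elsewhere. B and plasma cells were 8.31% of tumour 6 and at most 3.29% elsewhere. Neutrophils were 4.78% of tumour 4 and at most 1.43% elsewhere. In the copy number calls, which no comparison used as an outcome, 75.3% of the called macrophages and monocytes of tumour 6 were aneuploid, and at most 2.74% elsewhere.

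SREBF1 in hepatocyte-like cells was higher in tumours with more T cells (r = 0.826 on raw CPM). With TMM factors tumour 5, with 7.46% T cells, stood at 47.1 CPM and tumour 1, with 38.6%, at 45.8 CPM. The relation was not computed on that scale. RNA of other classes in the hepatocyte-like sums is argued against, since r was 0.820 after subtracting the SREBF1 that T cells, macrophages and endothelial cells would bring at their marker share. Chance stays open, with adjusted p = 0.567 over the 12 relations, and so does a batch of sequencing, since the library names of tumours 4 and 6 lack a mark of combination that the other 4 carry and its meaning is not stated. The T cell share and the hepatocyte-like share are parts of 1 total, and against the T cell share of the other cells r was 0.949 (exact permutation p = 0.00417, adjusted p = 0.05, range over alternatives 0.05 to 0.567). The design names no group of tumours, so no biological explanation was tested, and a link of SREBF1 to T cell numbers in either direction may exist only as a hypothesis.

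SREBP1 target and interferon response shares were inversely related across hepatocyte-like cells (mean excess −0.101, below 0 in 6 of 6 tumours). A common dependence on total RNA and mitochondrial share as the whole cause is argued against, since the partial rho given both was −0.0524 against −0.0606 without them, below 0 in 6 of 6 tumours (exact permutation p = 0.03125). Cells of other classes among the hepatocyte calls are argued against too, since the excess in hepatocyte clusters alone was −0.0939 (exact permutation p = 0.03125). Interferon-induced RNA from immune cells in the same droplets could still contribute, since without cells bearing immune UMIs only 3 tumours had enough cells, and their mean was −0.0531 (exact permutation p = 0.25, the smallest they allow). No biological explanation was tested.

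Aneuploid calls of tumour 6 fell on macrophages and monocytes (6114 of 8116 called cells) and on 40.7% of its called dendritic cells, but on 1.48% of its called hepatocyte-like cells. Copy number change spreads expression over chromosomes, and the SD over autosomes of the median log2 ratio to the other tumours was 0.0554 in these macrophages, against 0.0368 to 0.0547 in those of the other tumours and 0.159 to 0.342 in hepatocyte-like cells. The value lies just above the highest other macrophage value and below the bound set for a true change. It also lies within the range of T cells (0.0382 to 0.0567), of which 0.637% of called cells were aneuploid. No spread beyond that of such cells was thus seen. A true copy number change too small for this measure and a call made against the wrong reference cells cannot be told apart. A wrong reference was not tested itself, and may be a candidate explanation. No biological explanation was tested.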

How the results depend on the processing

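Alternatives with hepatocyte clusters only, aneuploid hepatocyte calls only, hepatocyte and epithelial calls together, and the mean of 10 thinning draws were chosen after the data were seen; the others were planned. The comparison of CD8 with CD4 T cells was not run, since the annotation does not separate them. Of the named gene results 2156 kept their direction and side of the threshold, 37 fell below it, 3 passed it and 16 reversed. Of the list counts 1980 stayed within 1.5 times the main count, 126 were smaller and 54 larger, and of the gene counts 100 stayed and 8 were smaller. The 10 results on shares stayed within their spread, 152 relations across tumours stayed and 16 reversed, and 23 relations within tumours stayed and 25 were no longer past the threshold. At the depth, trended spread and number of tumours of these sums, but with no tumour effect, simulated 1.5-fold changes were recovered in 8.96, 1.49 and 4.48% of genes and 2-fold changes in 31.3, 23.9 and 28.4%. The cause of a change was not tested except where stated.

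Leaving out cells with UMIs of at least 2 markers of another class left 2717 hepatocyte-like cells, 4477 T cells, 2520 macrophages and monocytes and 300 endothelial cells in 27 sums, so fewer cells and tumours are part of the cause by construction. Genes higher and lower were 3930 and 2531 against T cells, 3977 and 2189 against macrophages, and 1837 and 1604 against endothelial cells. SREBP1 targets higher and lower were 10 and 2 against T cells and 9 and 1 against endothelial cells, as were SREBP2 targets, while against macrophages 7 SREBP1 targets were higher and 1 SREBP2 target lower. Reversed against T cells were SREBF1 (−0.15), SREBF2 (−0.56), SCAP (−0.57) and DGAT1 (−0.18), against macrophages INSIG1 (−1.38), and against endothelial cells SREBF1 (−0.55), SREBF2 (−0.36), SCAP (−0.16) and INSIG1 (−0.026). No longer past the threshold were, against T cells, INSIG1, INSIG2, MBTPS2 and CXCL11, against macrophages SREBF2, SCAP and MBTPS2, and against endothelial cells MBTPS1, MBTPS2, EHHADH, DGAT2 and VSIR, with directions kept. Camera adjusted p of the SREBP1 list was 0.193, 0.370 and 0.116 in the 3 comparisons, with ranges of 6.09e-07 to 0.193, 1.63e-06 to 0.370 and 3.68e-10 to 0.116. The medians of that list were 1.29, 0.95 and 1.40. Against T cells SREBP2 had a median of 0.93 and adjusted p = 0.225 (range 3.92e-09 to 0.225), oxidation 1.15 and 0.0683 (7.03e-09 to 0.0683), and Wnt targets 1.71 and 0.219 (0.00128 to 0.219), and the median of lipid uptake turned to −0.27. Against macrophages the calls of cytotoxicity (−0.44, 0.611, range 0.00257 to 0.611), naive genes (−1.06, 0.370, range 0.0109 to 0.370) and Wnt targets (2.56, 0.466, range 0.000250 to 0.466) were lost, and the median of proliferation turned to 0.52. Against endothelial cells Wnt targets lost theirs (1.04, 0.291, range 2.71e-06 to 0.291) and the glycolysis median turned to 0.24. Gained there were MHC class II (−2.75, 8.56e-05, range 8.56e-05 to 0.540), interferon (−1.29, 0.000133, range 0.000133 to 0.223), lipid uptake (−0.97, 0.00531, range 0.00531 to 0.879) and TGF beta genes (−0.98, 0.0147, range 0.0147 to 0.252), and none held with an estimated correlation (adjusted p = 0.213, 0.246, 0.173 and 0.0906).

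With 2 classes in the fit, 4990 genes were higher than in T cells and 3242 than in endothelial cells, with 15993 and 14376 genes tested in 12 sums, fewer by construction. The endothelial comparison then had more lower than higher genes (3604), as it did with sums thinned to equal totals (4896 higher, 5100 lower). SREBP1 targets lower than in T cells were 2 with no count filter, 2 classes in the fit, the stricter cell filter, thinned sums, and hepatocyte and epithelial calls together, and 1 to 2 with 1 tumour left out. Against macrophages 0 were lower with DESeq2 size factors, the DESeq2 test, no block and hepatocyte clusters only, and 0 to 1 with 1 tumour left out. SREBF1 against macrophages, near 0, turned to 0.12 with DESeq2 size factors, 0.13 in the DESeq2 test, 0.16 without the block, 0.13 with aneuploid calls and 0.059 with epithelial calls added, and ran from −0.18 to 0.16 with 1 tumour left out. SREBF2 against T cells was not past the threshold with no count filter (0.55, adjusted p = 0.0514), 2 classes in the fit (0.47, 0.138) or the stricter filter (0.48, 0.0792), over a range of 0.00274 to 0.287. Without the block CCL21 (adjusted p = 0.128, range 2.69e-07 to 0.128) and IFI27 (0.0582, range 3.82e-12 to 0.0582) were not past it against endothelial cells, nor IFI44L against macrophages (0.0521, range 3.30e-08 to 0.0521).

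Across tumours, r of the SREBP2 list and chemokines turned to 0.139 with 0.1 CPM added and 0.159 with the stricter filter. That of the SREBP1 list and chemokines turned to −0.184, and that of the SREBP2 list and MHC class I to 0.0192, with the summed CPM of a list. That of the SREBP1 list and the CD8 share turned to −0.0108 with the stricter filter and −0.152 with aneuploid calls, which left out tumour 6 for want of cells, a step that by itself gave −0.0963. With 1 tumour left out, the SREBP1 list's r ran from −0.122 to 0.390 with the CD8 share and from −0.577 to 0.471 with MHC class I. The SREBP2 list's ran from −0.464 to 0.0745 with MHC class I and from −0.691 to 0.389 with chemokines, and that of SREBF1 from −0.307 to 0.735 with the CD8 share and from −0.763 to 0.134 with MHC class I. SREBF1 and the T cell share kept a positive r in all alternatives, from 0.823 to 0.949, and from 0.529 to 0.993 with 1 tumour left out. All of these used raw CPM, and none the TMM factors of the class comparisons, so the ranges do not cover that scale.

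Within tumours, cells thinned to 1000 UMIs gave −0.0565 for interferon and 0.0701 for oxidation (exact permutation p = 0.15625 each), and Pearson's r gave 0.238 for SREBP2 (exact p = 0.0625) and 0.0832 for oxidation (exact p = 0.09375). Without cells bearing immune UMIs the means were 0.159 for SREBP2 (exact p = 0.5), −0.0531 for interferon and 0.105 for oxidation (exact p = 0.25 each). Tumours 1, 4 and 6 then had 42, 10 and 15 cells and were left out, and 3 tumours cannot give an exact p under 0.25. With 1 tumour left out the means ran from 0.247 to 0.334 for SREBP2, from −0.121 to −0.0809 for interferon and from 0.0824 to 0.119 for oxidation, with p = 0.0625, the smallest exact permutation p that 5 tumours allow.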

Other observations

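The tests of exchanged classes were planned, and the levels by class and tumour given here were chosen after the data were seen and not tested. SREBF1 UMIs were also counted in other classes, at 24.9 ± 8.57 CPM in dendritic cells (SD, n = 6 tumours), 13.4 ± 5.37 in NK cells and 7.24 ± 4.77 in B and plasma cells, where the part due to free RNA was not measured. FASN, its main lipogenic target, was 112 ± 47.5 CPM in hepatocyte-like cells and between 5.64 and 13.6 in the other classes. SCD was 233 ± 121 CPM in hepatocyte-like cells, 73.8 ± 23.3 in macrophages and monocytes, 28.0 ± 12.2 in dendritic cells and 12 ± 4.37 in T cells. INSIG1 was 432 ± 215 CPM in dendritic cells and 367 ± 164 in macrophages and monocytes, against 102 ± 18.7 in NK cells. Among immune lists, the mean log2 level of cytotoxicity genes was 8.68 ± 0.38 in NK cells and 7.25 ± 0.46 in T cells, and that of dysfunction genes 4.88 ± 0.72 and 5.72 ± 1.06. MHC class II genes stood at 11.46 ± 0.41 in dendritic cells, 10.81 ± 0.43 in macrophages and monocytes and 9.07 ± 0.68 in B and plasma cells. T cell attracting chemokine genes stood at 6.25 ± 0.59 in macrophages and monocytes and 6.04 ± 0.78 in dendritic cells, and TGF beta and matrix genes at 7.43 ± 0.69 in mesenchymal cells (n = 5) and 6.67 ± 0.35 in endothelial cells.

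The hepatocyte-like cells of tumour 2 differed from those of the other tumours in markers of bile duct epithelium. Their KRT19 CPM was 523 and their EPCAM CPM 370, against 0 to 137 and 0.192 to 40.4 in the other tumours. Their ALB CPM was 3792 against 8224 to 113167, and their FASN CPM 18.7 against 113 to 146. In the epithelial cells of tumour 2 the same genes stood at 753, 526, 48.2 and 16.1 CPM.

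The compared classes were exchanged within tumours, in fits of the 2 classes alone. Against T cells 9133 genes were called, and 1 of the 32 exchanges, the real one, gave as many, with 0 as the highest of the others. Against macrophages and monocytes 9108 were called, in 1 of 32 exchanges, and the highest other gave 5. Against endothelial cells 6846 were called, in 1 of 32 exchanges, and the highest other gave 0. The classes had been called from the same expression values, so large counts for the real classes were given beforehand, and nothing further is read from these exchanges.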
